A study of Mus musculus with 60 samples.

How the data were processed

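Immunoglobulin light chain transcripts of sorted CD19+ B cells were sequenced in bulk from 60 samples of C57BL/6 mice, of which 56 were analysed here as separate libraries. Cells came from wild-type (WT) mice, from mice with a dominant-negative RAG1 transgene (dnRAG1), from mice with a VH12 heavy chain and from VH12-dnRAG1 mice. Per the labels, cells were sorted by CD5 and by binding of phosphatidylcholine (PtC) liposomes, and those of the bone marrow also by AA4.1. Mouse numbers in the sample titles show that each library came from a pool of 1 to 3 mice and that different replicates came from different mice. The titles place the samples in 2 rounds: round 1 held spleen samples of every genotype, and round 2 held bone marrow and spleen samples of VH12 and VH12-dnRAG1 mice.

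Per the submitters' processing notes, bcl2fastq 2.20 and R 3.6.0 were used upstream. The aligner, the caller of gene segments and the germline set are not given in the sources used here. The deposited files list 1 unique sequence per line, and per the file headers the counts are the reads (CONSCOUNT) and the collapsed molecules (DUPCOUNT) behind each sequence. The V identity column is, per the file headers, a fraction of aligned V bases equal to the germline, and an unread base lowered it, so mismatches were recounted at bases that had been read. Columns of N/P nucleotides and junction length in the deposited files were other values, in nucleotides. The values had no normalization. Every sequence in the files was productive (0 were not) and had at least 2 reads. The 56 files held 219735 sequences, of which 192194 were kappa (IGK), 27540 lambda (IGL) and 1 heavy chain (IGH). The IGH sequence was left out of all shares. Samples not analysed here were WT replicate 3, dnRAG1 CD5-PtC- replicate 2, dnRAG1 CD5+PtC- replicate 3 and VH12-dnRAG1 bone marrow AA4.1+ CD5-PtC- replicate 2.

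Molecules were summed per library and gene. Gene names are the IMGT names in the files. Where a call listed several V genes, the first was taken (0.472% of the IGK sequences). A share is a percentage of the IGK molecules of a library unless another base is named, and the lambda share is a percentage of the light chain molecules. A clonotype is a combination of V gene, J gene and junction nucleotides. The effective number of genes or clonotypes is the exponential of the Shannon entropy, which for clonotypes was taken after 2000 molecules had been drawn from each library (seed 1). Clonotype overlap is the sum of the smaller of the shares in a pair of libraries. The locus was divided by the position in the IMGT name: J-proximal genes have positions up to 45, middle genes up to 91 and J-distal genes up to 137. Libraries held 2566 to 95109 molecules, and the intervals of single shares are Wilson intervals at 95% that cover counting error only.

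V gene usage was compared in 16 pairs of groups with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Counts were molecules per IGKV gene, the library size was the total of IGK molecules with normalization factors of 1, and genes with a mean share of at least 0.1% over the libraries compared were tested. Each fit held the groups compared, with round as covariate where the spleen libraries of both rounds were used and genotype as covariate where both genotypes were pooled. The test was the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The standard error (SE) of a log2 fold change was taken from the F statistic. Other measures were compared in 20 pairs of groups by exact two-sided permutation of the libraries within round or genotype, and p was adjusted by Benjamini-Hochberg over the 20 comparisons of a measure. With 3 libraries against 3 or 2 the smallest permutation p is 0.1, with 2 against 2 it is 0.333, and with 6 against 6 in strata of 3 it is 0.005. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.

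The groups, comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Named were the 5 genes singled out in the labels (IGKV3-7, IGKV4-91, IGKV4-86, IGKV1-110 and IGKV14-126) in every V gene comparison. Named in addition were genes past the threshold with a mean share of at least 1% in either group. These were up to the 10 highest and 10 lowest log2 fold changes in the main spleen comparisons and up to 3 of each elsewhere. The lists were the IGKV families, the parts of the locus, the IGKJ genes, the 5 label genes and the textbook PtC light chain genes IGKV4-91 (partner of VH12) and IGKV14-126 (partner of VH11). The assay holds no markers of other cell types. No genome came with the series, so no coordinates are given. The order of the genes in their names was checked against the RefSeq annotation, which held 99 of the 100 IGKV genes seen.

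Arms of the comparisons between gates or tissues came from the same mice, as the mouse numbers in the titles show. As a check of this pairing, deviations of log2 V gene shares from the group mean were correlated across genes (Pearson's r) between libraries of the same and of different mice. The median r was 0.388 for the same and -0.207 for different mice between spleen and marrow AA4.1- CD5-PtC- cells, and 0.473 and -0.450 in CD5+PtC+ cells. It was 0.292 and -0.175 in dnRAG1 spleen, 0.125 and -0.0685 in VH12 spleen, 0.0958 and -0.0435 in VH12-dnRAG1 spleen, and -0.272 and 0.147 in VH12 marrow AA4.1+ cells. For the same mice it was 0.0654 between dnRAG1 CD5+PtC- and CD5-PtC- cells and -0.169 in VH12-dnRAG1 marrow AA4.1+ cells. In marrow AA4.1- cells it was 0.0882 in VH12 and -0.218 in VH12-dnRAG1 mice. Between marrow AA4.1- and AA4.1+ it was 0.231 in CD5-PtC- and 0.0462 in CD5+PtC+ cells. Deviations from a group mean sum to 0, so r between different mice tends to the opposite sign by construction and adds no evidence. Fits with the mouse pool as a block, and exact sign-flip tests of the differences per pool, were run as an alternative.

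Alternatives tried were edgeR's TMM factors, DESeq2 1.42.0 with its own size factors, no filter on low shares, all libraries of the rounds in 1 fit and the mouse pool as a block. Others were each unique sequence counted once, each clonotype counted once, ambiguous V calls left out, libraries drawn down to a fixed depth, each round alone, another clonotype definition, the Morisita-Horn index and each library left out in turn. Leaving out doubted libraries was added after the data had been seen: VH12 spleen CD5+PtC+ replicate 3 and VH12-dnRAG1 spleen CD5-PtC- replicate 4 for their V usage, and replicate 3 of dnRAG1 spleen CD5-PtC- and CD5+PtC+ for low base quality, which the VH12 library had as well. In these 3 libraries 97.6% to 99.8% of sequences held insertions or deletions, and there was about 1 molecule per sequence against 2.24 to 22.7 in the others, so their shares are in effect shares of unique sequences. Keeping sequences that are not productive could not be tried, because the files hold none.

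The V gene test was tested on simulated data with 20 changed genes per comparison. At a fold of 16 it recovered 20 of them for VH12 against WT (1 false call), VH12-dnRAG1 spleen CD5+PtC+ against CD5-PtC-, VH12-dnRAG1 against VH12 spleen CD5-PtC- (1 false call), VH12 marrow AA4.1+ CD5+PtC+ against CD5-PtC- and marrow AA4.1- against AA4.1+ CD5+PtC+. It recovered 4 in dnRAG1 CD5+PtC+ against CD5-PtC-. At a fold of 4 the numbers recovered were 3, 2, 19, 18 and 20 in the same order, and 0 in the dnRAG1 comparison. In the real data 44 of 47 genes passed between the gates of VH12-dnRAG1 spleen. In marrow AA4.1- against AA4.1+ CD5+PtC+ cells 51 of 52 passed. Simulated sets with 20 changed genes do not cover such a shift of nearly all shares. The numbers recovered and the false calls therefore say nothing on the test in that setting.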

Results

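Light chain repertoires were measured in B cells sorted from the spleen and bone marrow of mice that differ in heavy chain and in recombination activity. VH12 mice carry a rearranged heavy chain gene whose B cells bind PtC, a membrane phospholipid, when VH12 is paired with a suitable light chain. The dnRAG1 transgene encodes a catalytically inactive RAG1 protein that competes with the recombinase. CD5 marks B-1a cells, PtC liposomes mark cells with PtC-binding receptors, and AA4.1 marks immature B cells. Spleen cells were sorted as CD5-PtC- from WT (n = 2) and dnRAG1 mice (n = 2), as CD5+PtC- (n = 2) and CD5+PtC+ (n = 3) from dnRAG1 mice, and as CD5-PtC- and CD5+PtC+ from VH12 and VH12-dnRAG1 mice (n = 6 each, 3 per round). Bone marrow AA4.1+ and AA4.1- cells were sorted into the same 2 gates from VH12 and VH12-dnRAG1 mice (n = 3 each, and n = 2 for VH12-dnRAG1 AA4.1+ CD5-PtC-). In these mice the 2 gates differ in CD5 and in PtC binding at once. Comparisons between the PtC gates therefore cannot tell these traits apart.

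Libraries of round 1 held 10548 to 76585 molecules in WT, 2566 to 12391 in dnRAG1 CD5-PtC-, 10292 to 52970 in dnRAG1 CD5+PtC- and 6175 to 27976 in dnRAG1 CD5+PtC+ cells. Spleen libraries of both rounds held 7939 to 65177 molecules in VH12 CD5-PtC-, 8169 to 80204 in VH12 CD5+PtC+, 6938 to 38680 in VH12-dnRAG1 CD5-PtC- and 9729 to 95109 in VH12-dnRAG1 CD5+PtC+ cells. In marrow AA4.1+ cells the CD5+PtC+ libraries were the smallest, with 4292 to 5757 molecules in VH12 and 3409 to 6225 in VH12-dnRAG1, against 18294 to 22482 and 13702 to 24444 in CD5-PtC- libraries. Marrow AA4.1- libraries held 18750 to 36551 (VH12) and 6769 to 25458 (VH12-dnRAG1) molecules in CD5-PtC- cells, and 31271 to 54787 and 28606 to 71272 in CD5+PtC+ cells. There were 1.01 to 20.8 reads per molecule. Values below are means ± SD over libraries, and the adjusted p of a V gene is from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment.

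The first question was which light chains PtC-binding B cells use when the heavy chain is not fixed. In dnRAG1 spleen, IGKV14-126, the textbook partner of the VH11 heavy chain in PtC receptors, rose in CD5+PtC+ cells to 35.5% ± 10.1 (n = 3) from 0.612% ± 0.108 in CD5-PtC- cells (n = 2; log2 fold change 5.86, SE 0.64, adjusted p = 0.00205). IGKV4-91, the textbook partner of VH12, rose to 10.2% ± 5.45 from 1.49% ± 0.225 (log2 2.77, adjusted p = 0.0479). IGKV3-7 took 7.42% ± 5.45 against 1.33% ± 0.136 (adjusted p = 0.0645, and 0.0212 with the mouse pool as a block). CD5+PtC- cells held 8.15% ± 2.77 IGKV4-91, 0.117% IGKV14-126 and 0.146% IGKV3-7 (n = 2). The rise of IGKV4-91 therefore cannot be assigned to PtC binding. The CD5+PtC+ and CD5+PtC- cells were not tested against each other. Among genes that are common in CD5-PtC- cells, IGKV1-110 fell to 1.46% from 7.78%, IGKV1-135 to 1.05% from 6.25% and IGKV3-4 to 0.0468% from 2.79% (log2 -5.75). Also lower were IGKV17-121 (log2 -3.51), IGKV4-59 (-3.44), IGKV4-68 (-3.03), IGKV5-39 (-3.01) and IGKV8-24 (-2.78). IGKV4-86 stood at 0.389% and 0.954% (adjusted p = 0.324), a direction that turned with TMM scaling (log2 0.66). The most frequent IGKV14-126 junction in dnRAG1 CD5+PtC+ cells was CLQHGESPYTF, which joins to IGKJ2 and made up 51.9% ± 13.5 of IGKV14-126 molecules.

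By list, 2 of the 5 label genes rose and 1 fell in this comparison, and 4 passed when adjusted over the list alone. The study chose those genes on these samples, so their count is not independent evidence. Of the IGKV4 family 1 of 19 members rose and 2 fell, of the IGKV1 family 2 of 5 fell, and 3 of 23 J-proximal genes and 3 of 18 J-distal genes fell, with 1 J-distal gene up. The J-distal list had 7 calls when adjusted over the list alone. The effective number of IGKV genes was 11.4 ± 3.24 against 44.2 ± 0.970 (exact permutation p = 0.1, the smallest possible). IGKJ4 and IGKJ5 together took 49.7% ± 4.25 and 41.7% ± 1.76 (exact p = 0.1). In all, 2 of 61 genes rose and 8 fell, and 26 had an unadjusted p under 0.05. The count rests on few libraries: it was 0 without CD5-PtC- replicate 1, 2 without CD5-PtC- replicate 3, and 27, 17 and 18 without CD5+PtC+ replicates 1, 2 and 3. Replicate 3 of both gates had low base quality, and without this pair IGKV14-126 alone passed (adjusted p = 0.0439) and IGKV4-91 did not (0.597). With the mouse pool as a block 10 genes passed, 4 up and 6 down, and IGKV17-121 (0.0850), IGKV4-68 (0.116) and IGKV8-24 (0.116) did not. With TMM scaling (median shift of the log2 change 1.94) 3 genes were up and 0 down, and with DESeq2 6 up and 1 down.

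CD5+ cells that did not bind PtC were compared with CD5-PtC- cells as well. In dnRAG1 spleen CD5+PtC- cells IGKV14-126 held 0.117% ± 0.0324 against 0.612% in CD5-PtC- cells, IGKV3-7 held 0.146% against 1.33%, and IGKV4-91 held 8.15% ± 2.77 against 1.49% (n = 2 each; adjusted p = 0.188, 0.169 and 0.169). IGKV1-110 was at 8.24% and 7.78%, and IGKV4-86 at 0.725% and 0.954% (adjusted p = 0.937 and 0.835), and the direction of IGKV4-86 turned with TMM scaling (log2 0.71). Lambda chains made up 52.4% ± 8.95 of light chain molecules in CD5+PtC- cells and 19.9% ± 6.73 in CD5-PtC- cells (exact permutation p = 0.333, the smallest that 2 against 2 allow). With edgeR 0 of 62 genes passed, 15 had an unadjusted p under 0.05, and DESeq2 called 4. Without CD5+PtC- replicate 1 or 2 edgeR called 34 or 45 genes, with the remaining library assumed to vary like the other group. Adjusted over the list alone, 2 of the 5 label genes, 3 of 7 IGKV3 genes and 2 of 2 IGKV17 genes passed.

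The dnRAG1 transgene alone was compared with WT in spleen CD5-PtC- cells. IGKV1-110 held 7.78% ± 0.240 in dnRAG1 and 8.74% ± 0.735 in WT, IGKV4-91 1.49% ± 0.225 and 1.65% ± 0.101, and IGKV14-126 0.612% ± 0.108 and 0.689% ± 0.218 (n = 2 each). IGKV3-7 held 1.33% and 0.919%, and IGKV4-86 0.954% and 0.852%. The adjusted p of these 5 genes ranged from 0.699 to 0.966. With edgeR 0 of 67 genes passed, 5 had an unadjusted p under 0.05, and DESeq2 called 0. The IGKJ4 and IGKJ5 genes together took 41.7% ± 1.76 and 38.0% ± 0.159 (exact permutation p = 0.333, the smallest possible). In the IGKV1 family 1 of 6 members passed when adjusted over the list alone.

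Whether the VH12 heavy chain shapes light chains in cells outside the PtC gate was asked by comparing VH12 with WT spleen CD5-PtC- cells of round 1. IGKV4-86 rose to 12.7% ± 1.39 (n = 3) from 0.852% ± 0.47 (n = 2; log2 3.88, SE 0.41, adjusted p = 4.64e-05) and IGKV5-43 to 12.3% ± 5.16 from 2.14% ± 0.230 (log2 2.52). IGKV4-58 rose to 5.78% from 0.428%, IGKV1-122 to 3.69% from 0.421%, and IGKV1-110 to 15.96% ± 1.15 from 8.74% ± 0.735 (adjusted p = 0.00676). Those that fell were IGKV9-120 (0.552% from 4.59%), IGKV1-117 (2.18% from 7.13%), IGKV3-4 (log2 -3.13), IGKV6-32 (log2 -3.31) and IGKV17-121 (log2 -2.28). IGKV4-91 was at 3.75% ± 1.81 and 1.65% ± 0.101 (adjusted p = 0.136), IGKV14-126 at 0.126% and 0.689% (0.0719), and IGKV3-7 at 0.534% and 0.919% (0.453; log2 0.18 with TMM scaling). The downstream IGKJ4 and IGKJ5 genes together took 60.3% ± 7.04 in VH12 and 38.0% ± 0.159 in WT cells (exact permutation p = 0.1, the smallest possible).

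Of the 5 label genes 2 rose against WT, and 3 passed when adjusted over the list alone. In the IGKV4 family 2 of 18 members rose, in the IGKV1 family 2 of 6 rose and 1 fell, and of 20 J-distal genes 2 rose and 3 fell, with 12 calls when adjusted over the list alone. In all, 5 of 62 genes rose and 5 fell, and 27 had an unadjusted p under 0.05. The count was 3 or 4 without WT replicate 1 or 2, 15, 28 and 4 without VH12 replicates 1, 2 and 3, and 0 with all libraries of round 1 in 1 fit. With TMM scaling (median shift 0.97) 9 genes were up and 1 down, and with DESeq2 10 up and 3 down.

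In VH12 spleen, IGKV4-91 rose in CD5+PtC+ cells to 78.6% ± 37.2 from 6.50% ± 3.28 in CD5-PtC- cells (n = 6 each; log2 3.71, SE 0.89, adjusted p = 0.0164). It was higher in 6 of 6 mouse pools (exact sign-flip p = 0.0312, the smallest possible). In 5 of the CD5+PtC+ libraries IGKV4-91 made up 86.3% to 98.2%, and in replicate 3 it made up 3.24% (Wilson interval at 95%, 2.84% to 3.69%). The CD5-PtC- library of the same mice as replicate 3 held 2.45%. That pool thus rose by 0.786 percentage points, against 83.3 to 92.4 in the other pools. IGKV1-110 held 2.39% ± 5.63 against 14.1% ± 2.50 and IGKV4-86 2.22% ± 5.07 against 11.8% ± 2.03 (adjusted p = 0.0593 each, and 9.48e-05 and 0.000361 with the mouse pool as a block). IGKV3-7 held 2.83% ± 3.50 against 0.714% ± 0.367 (adjusted p = 0.122). The other gene past the threshold was IGKV3-10 (0.0199% against 0.377%, log2 -4.23, adjusted p = 0.0380), which lies outside the rule for named genes and was picked after its values were seen.

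**Figure D1:**
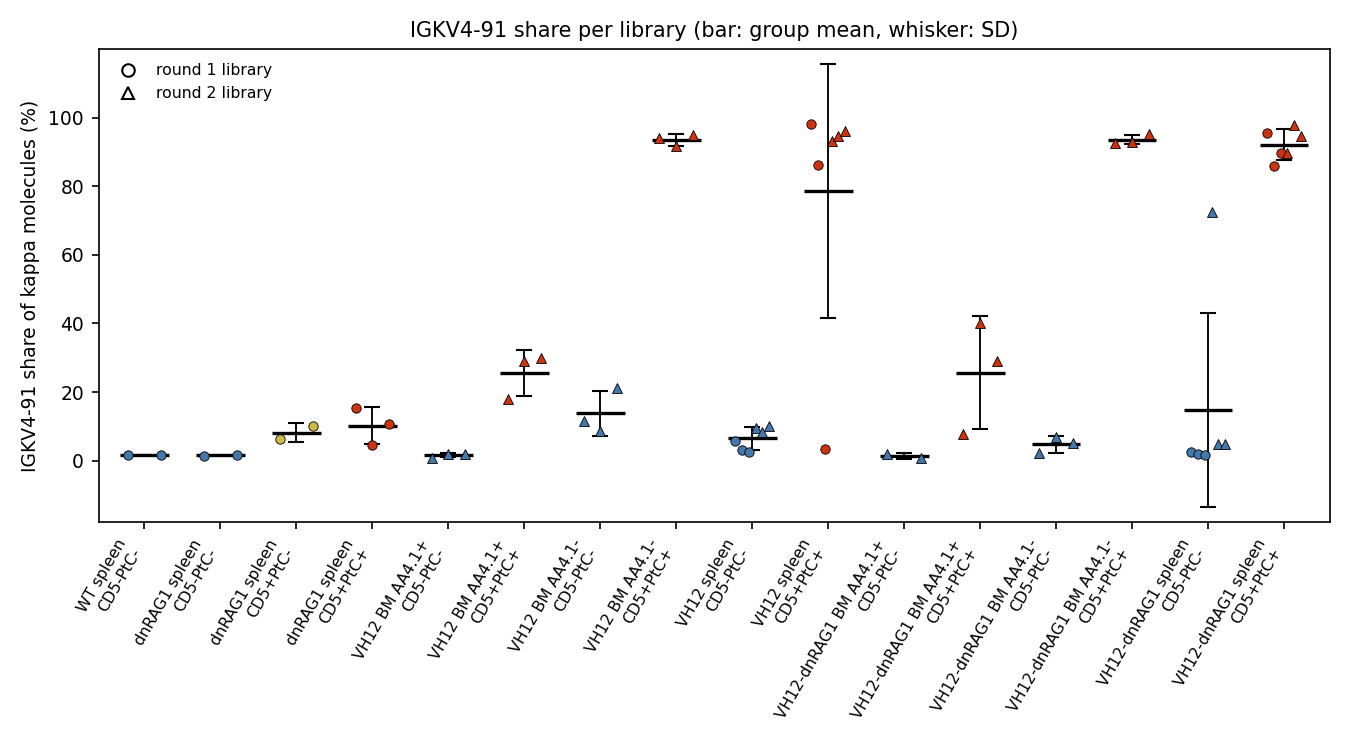
IGKV4-91 share of kappa molecules in percent (vertical axis) in each library of the 16 sorted populations (horizontal axis); circles are round 1, triangles round 2, blue CD5-PtC-, yellow CD5+PtC- and red CD5+PtC+ cells, with bars at the group mean and whiskers of 1 SD. VH12 and VH12-dnRAG1 CD5+PtC+ cells of spleen and marrow AA4.1- sit at 85.8% or more, except VH12 spleen replicate 3 at 3.24%, and VH12-dnRAG1 spleen CD5-PtC- replicate 4 stands at 72.6%.

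Single libraries decide how many genes pass in VH12 spleen, replicate 3 most of all. With all libraries 1 of 53 genes rose and 1 fell, and 37 had an unadjusted p under 0.05. Without CD5+PtC+ replicate 3 there were 52 past the threshold, 2 up and 50 down, and without CD5+PtC+ replicate 1 there were 37. Without CD5-PtC- replicate 2, and without CD5+PtC+ replicate 2 or 4, there were 0, so the call of IGKV4-91 was lost. Without CD5+PtC+ replicate 3 IGKV4-91 stood at 93.7% (adjusted p = 1.63e-08), IGKV1-110 and IGKV4-86 fell (1.63e-08 each) and IGKV3-7 rose (log2 2.16, adjusted p = 0.00515). With the mouse pool as a block 1 gene rose and 49 fell. Round 1 gave 0 genes (edgeR, 0 with an unadjusted p under 0.05) and round 2 gave 49; the IGKV4-91 shares were 62.6% ± 51.7 against 3.75% ± 1.81 in round 1 and 94.7% ± 1.40 against 9.26% ± 0.90 in round 2. Among the lists, 1 of 4 tested label genes passed (3 when adjusted over the list alone), 1 of 18 IGKV4 genes rose, and 0 of 4 IGKV5 genes passed (4 when adjusted over the list alone).

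In VH12-dnRAG1 spleen the same gene dominated the PtC gate. IGKV4-91 rose to 92.2% ± 4.55 in CD5+PtC+ cells from 14.8% ± 28.4 in CD5-PtC- cells (n = 6 each, log2 3.6, SE 1.12, adjusted p = 0.00293), in 6 of 6 pools (exact sign-flip p = 0.0312). The rise was 17.1 percentage points in the pool of CD5-PtC- replicate 4 and 83.8 to 93.1 in the other pools. Genes that are common in CD5-PtC- cells became scarce: IGKV5-43 fell to 0.0830% from 16.9%, IGKV1-110 to 0.153% from 13.8%, IGKV4-86 to 0.217% from 8.22% and IGKV1-122 to 0.0305% from 4.34%. IGKV5-48 (log2 -7.45), IGKV4-58 (-6.28), IGKV4-57-1 (-6.20), IGKV8-24 (-5.95), IGKV4-68 (-4.42) and IGKV4-59 (-4.31) fell as well. IGKV3-7 kept a share of 2.88% ± 2.25 against 1.82% ± 3.16 (adjusted p = 0.351), and its direction turned in round 2 alone (log2 -0.46). Without CD5-PtC- replicate 4, in which IGKV4-91 made up 72.6% (Wilson interval 71.9% to 73.3%), the IGKV4-91 mean in CD5-PtC- cells was 3.19%, the log2 change 4.91, and IGKV3-7 passed (log2 2.55, adjusted p = 0.00569).

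Of 47 genes tested in VH12-dnRAG1 spleen 1 rose and 43 fell. These included 12 of 14 IGKV4 genes, 4 of 5 IGKV1, 4 of 4 IGKV5, 5 of 5 IGKV6, 5 of 5 IGKV8 and 4 of 5 IGKV3 genes, and 12 of 13 J-distal, 13 of 15 middle and 18 of 19 J-proximal genes. Of 4 tested label genes 1 rose and 2 fell. These are shares of all kappa molecules, of which IGKV4-91 took most in CD5+PtC+ cells. Most other shares therefore had to fall, and the counts are no evidence on single families or parts of the locus. With TMM scaling, which moves the median log2 change by 3.40 here and by 2.16 in VH12 spleen, 9 genes were up and 13 down, and with DESeq2 8 were up and 21 down. Round 1 gave 40 genes and round 2 gave 36, and the IGKV4-91 shares were 90.4% ± 4.92 against 2.10% ± 0.479 and 94.1% ± 4.15 against 27.4% ± 39.1. The effective number of IGKV genes was 1.64 ± 0.387 in CD5+PtC+ and 17.5 ± 6.75 in CD5-PtC- cells of VH12-dnRAG1 mice (exact permutation p = 0.005, the smallest possible; adjusted p = 0.05; lower in 6 of 6 pools). In VH12 mice it was 5.54 ± 9.99 and 22.7 ± 4.07 (exact permutation p = 0.015, adjusted p = 0.1; exact sign-flip p = 0.0625), and 1.46 in CD5+PtC+ cells without replicate 3.

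**Figure D2:**
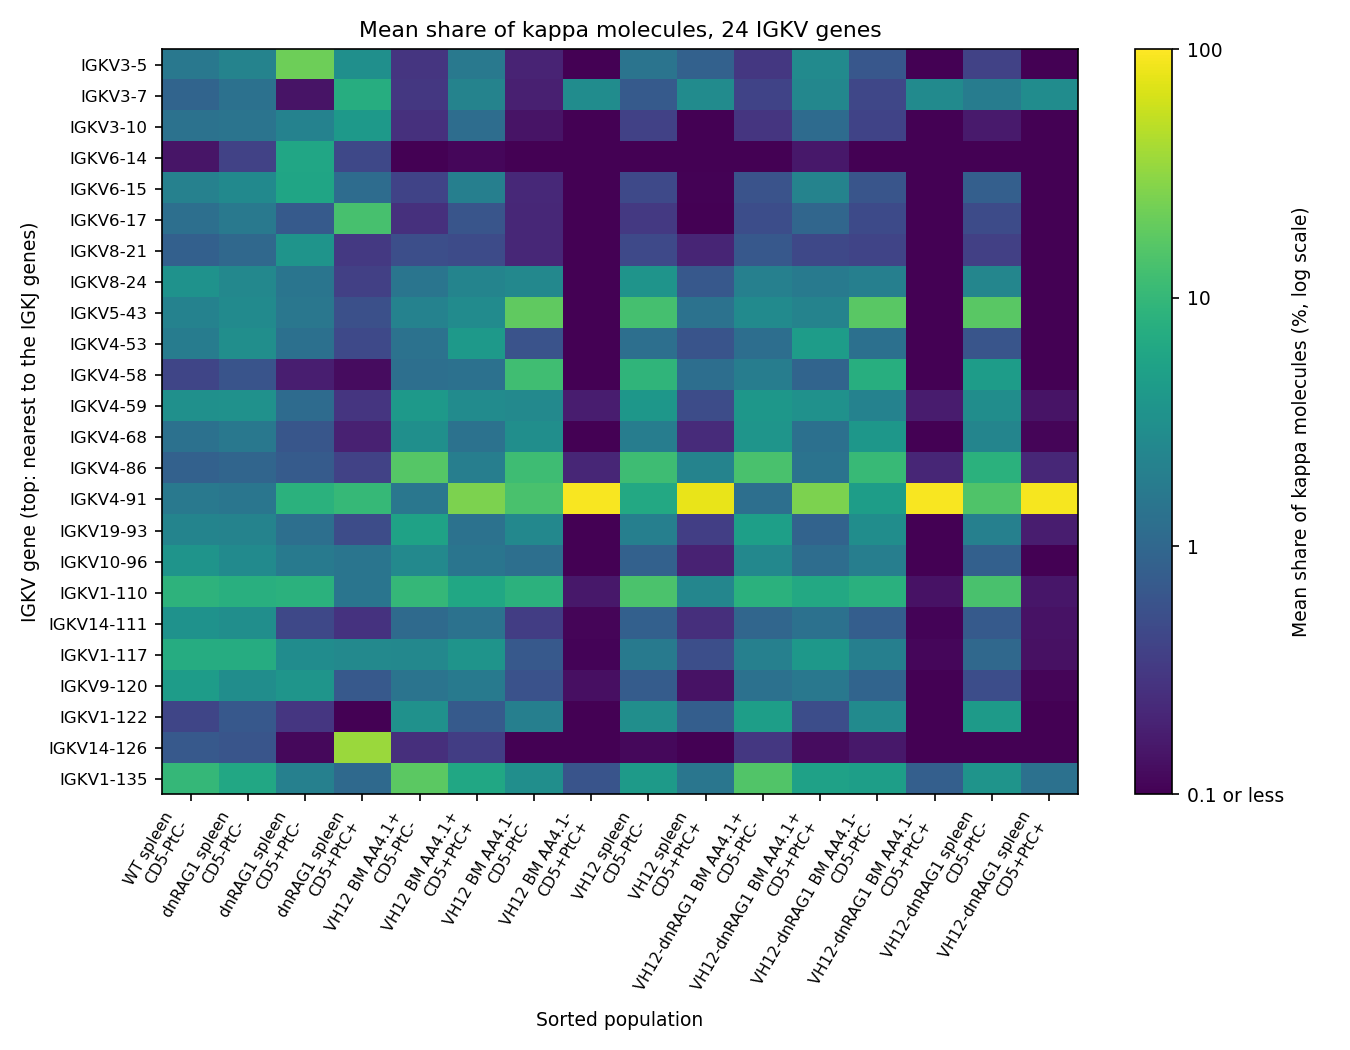
Mean share of kappa molecules in percent (colour, log scale, 0.1% or less in the darkest shade) of 24 IGKV genes (vertical axis, from nearest to farthest from the IGKJ genes) in the 16 sorted populations (horizontal axis). IGKV14-126 reaches 35.5% in dnRAG1 CD5+PtC+ cells, and IGKV4-91 reaches 93.6% in marrow AA4.1- CD5+PtC+ cells of both VH12 genotypes.

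Whether dnRAG1 alters the light chains of VH12 mice was tested in each gate of the spleen. In CD5+PtC+ cells IGKV4-91 held 92.2% ± 4.55 in VH12-dnRAG1 and 78.6% ± 37.2 in VH12 mice (adjusted p = 0.834), and 93.7% in VH12 without replicate 3. IGKV3-7 held 2.88% and 2.83% (0.990, and log2 -0.38 with TMM scaling), IGKV1-110 0.153% and 2.39%, and IGKV4-86 0.217% and 2.22% (0.762 each). VH12 replicate 3 held 13.9% IGKV1-110 and 12.6% IGKV4-86, and the other VH12 libraries at most 0.246% and 0.263%. Without replicate 3 the directions of IGKV4-91, IGKV3-7, IGKV1-110 and IGKV4-86 turned. With edgeR 0 of 27 genes passed, 0 had an unadjusted p under 0.05, and DESeq2 called 0 with 4 at an unadjusted p under 0.05. Fitted with all libraries of both rounds, 12 genes were lower in VH12-dnRAG1. None of the lists held a call in this comparison.

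In CD5-PtC- cells of the spleen IGKV4-61 fell in VH12-dnRAG1 mice to 0.0804% from 0.308% (log2 -1.95, adjusted p = 0.0120). It was the only gene of 56 past the threshold and the only 1 of 17 IGKV4 members; it lies outside the rule for named genes and was picked after its values were seen. At an unadjusted p under 0.05 there were 4 genes, and each round alone gave 0, with 9 in round 1 and 2 in round 2 at an unadjusted p under 0.05. IGKV1-110 held 13.8% ± 6.76 and 14.1% ± 2.50 (adjusted p = 0.916; log2 0.083 with TMM scaling), IGKV4-86 8.22% ± 4.45 and 11.8% ± 2.03 (0.737), IGKV3-7 1.82% and 0.714% (0.573) and IGKV14-126 0.0938% and 0.115% (0.766; log2 0.056 with TMM scaling). IGKV4-91 held 14.8% ± 28.4 and 6.50% ± 3.28 (0.823), but without VH12-dnRAG1 replicate 4 the direction turned: 3.19% against 6.50%, log2 -0.88, adjusted p = 0.0365, and 4 genes passed. Without VH12-dnRAG1 replicate 4 the directions of IGKV3-7 and IGKV1-110 turned as well. That library held 8.25% IGKV3-7, and the others of its group 0.273% to 0.886%. Leaving out VH12-dnRAG1 replicate 3 or VH12 replicate 5 gave 0 genes. The rise of IGKV4-91 between the gates was 77.5 ± 29.8 percentage points in VH12-dnRAG1 and 72.1 ± 35.1 in VH12 mice, a difference of 5.33 (exact permutation p = 0.565, two-sided). Round 2 alone turned it to -18.8.

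Use of the downstream IGKJ4 and IGKJ5 genes, which secondary rearrangements reach, was compared next. In VH12-dnRAG1 spleen they took 88.7% ± 5.95 in CD5+PtC+ and 70.3% ± 5.06 in CD5-PtC- cells (exact permutation p = 0.005, adjusted p = 0.05), higher in 6 of 6 pools. In VH12 spleen they took 78.4% ± 11.6 and 64.2% ± 6.64 (exact p = 0.02, adjusted p = 0.1), also in 6 of 6 pools. Within rounds the VH12 shares were 72.8% against 60.3% and 84.0% against 68.0%, and the VH12-dnRAG1 shares 88.3% against 67.0% and 89.1% against 73.5%. IGKJ5 by itself took 82.1% ± 8.45 against 51.5% ± 11.3 in VH12-dnRAG1 (exact p = 0.005, adjusted p = 0.0333, 6 of 6 pools) and 63.1% ± 16.9 against 41.7% ± 5.39 in VH12 spleen (exact p = 0.015, adjusted p = 0.075, 6 of 6 pools). IGKJ1 took 4.18% against 16.7% in VH12-dnRAG1 (exact p = 0.005, adjusted p = 0.0333, lower in 6 of 6 pools), IGKJ2 7.10% against 13.1% and IGKJ4 6.66% against 18.7% (exact p = 0.04 and 0.015, adjusted p = 0.133 and 0.075).

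In VH12-dnRAG1 spleen CD5+PtC+ libraries the part outside IGKV4-91 was small. IGKV4-91 held 85.8% to 97.9% of kappa molecules, and IGKV3-7 another 0.517% to 6.22%. Outside IGKV4-91 the order of the gates was the opposite. There IGKJ4 and IGKJ5 took 29.2% ± 3.25 in VH12-dnRAG1 CD5+PtC+ cells and 62.4% ± 13.7 in CD5-PtC- cells (exact permutation p = 0.005, adjusted p = 0.0333, lower in 6 of 6 pools). In VH12 spleen the shares were 32.1% ± 13.6 and 63.7% ± 6.67 (exact p = 0.015, adjusted p = 0.075). Between genotypes, the IGKJ4 and IGKJ5 share of all kappa molecules was 88.7% in VH12-dnRAG1 and 78.4% in VH12 CD5+PtC+ cells (exact p = 0.07) and 70.3% against 64.2% in CD5-PtC- cells (exact p = 0.065; adjusted p = 0.167 each). Counting each clonotype once, the gates differed by 1.41 percentage points in VH12 (exact p = 0.335) and by 4.67 in VH12-dnRAG1 spleen (exact p = 0.09).

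**Figure D3:**
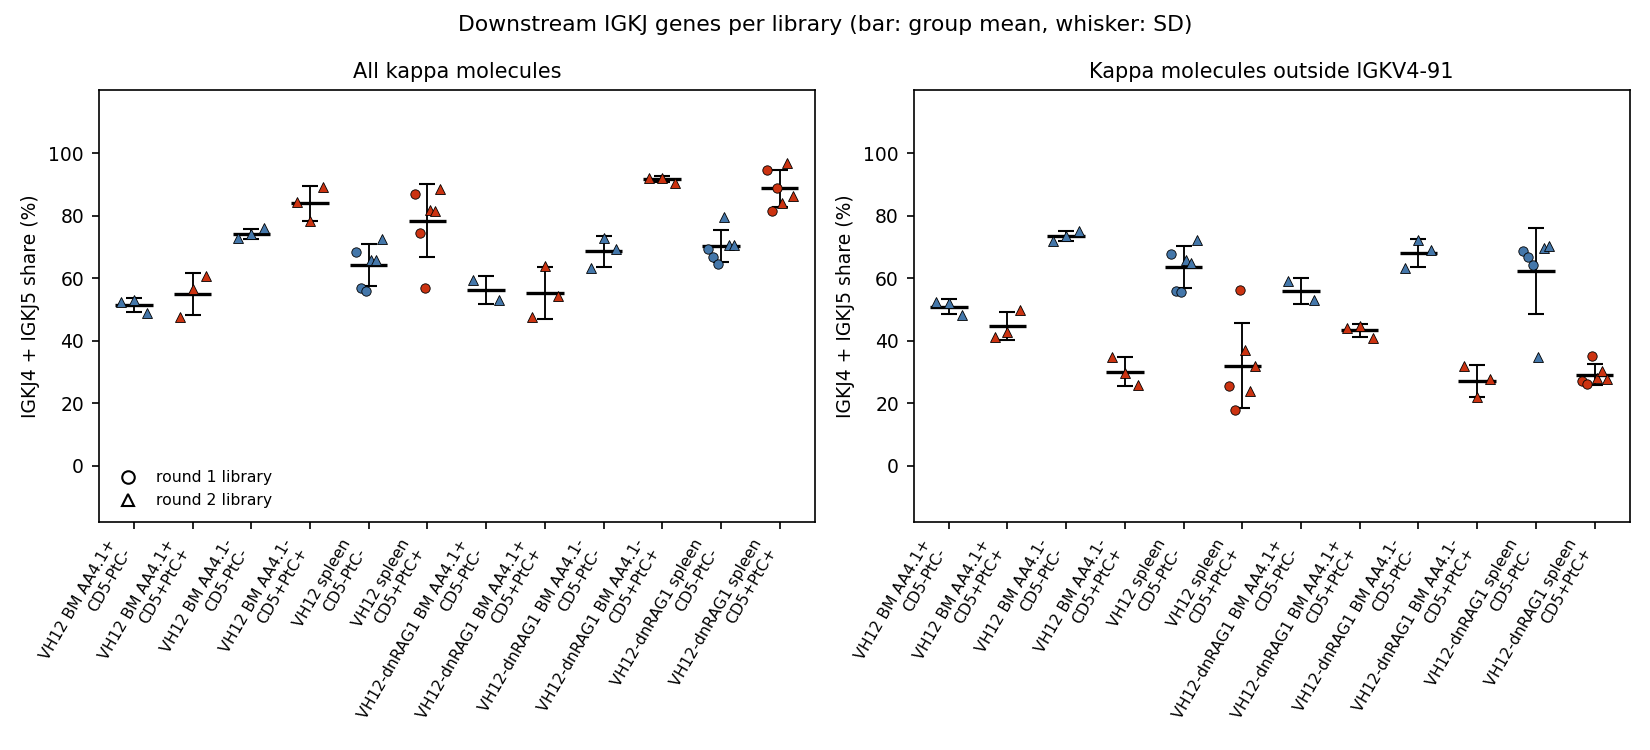
Share of IGKJ4 and IGKJ5 in percent (vertical axes) of all kappa molecules (left) and of those outside IGKV4-91 (right) in each library of the VH12 and VH12-dnRAG1 populations; circles are round 1, triangles round 2, blue CD5-PtC- and red CD5+PtC+, with bars at the mean and whiskers of 1 SD. VH12-dnRAG1 spleen CD5+PtC+ cells average 88.7% on the left and 29.2% on the right.

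The IGKV4-91 chains themselves differed in their joins. The leading junction in spleen CD5+PtC+ cells was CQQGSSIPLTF, a join to IGKJ5, with 86.2% ± 5.62 of IGKV4-91 molecules in VH12-dnRAG1 and 58.7% ± 27.2 in VH12 mice (69.3% ± 8.50 without replicate 3, which held 5.32%; exact permutation p = 0.005, adjusted p = 0.1, also 0.005 without it), and no VH12 library reached the lowest VH12-dnRAG1 one. In CD5-PtC- cells it held 45.9% ± 27.8 in VH12-dnRAG1 and 15.9% ± 6.10 in VH12 mice (exact p = 0.025, adjusted p = 0.125). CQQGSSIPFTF, a join to IGKJ4, led in VH12 CD5-PtC- cells with 30.7% ± 3.17, against 14.9% ± 8.25 in VH12-dnRAG1 (exact p = 0.005, adjusted p = 0.05). In CD5+PtC+ cells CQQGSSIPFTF held 13.6% ± 14.7 in VH12 and 1.90% ± 1.62 in VH12-dnRAG1 mice (exact p = 0.01, adjusted p = 0.05), and 7.77% in VH12 without replicate 3. The same junction led in WT (31.7% ± 3.86) and dnRAG1 CD5-PtC- cells (40.7% ± 0.975). In dnRAG1 CD5+PtC- cells it held 43.7% ± 12.9 and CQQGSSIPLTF 34.8% ± 12.1, and in dnRAG1 CD5+PtC+ cells 34.3% ± 20.6 and 35.6% ± 22.3, or 22.7% and 47.4% without replicate 3.

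**Figure D4:**
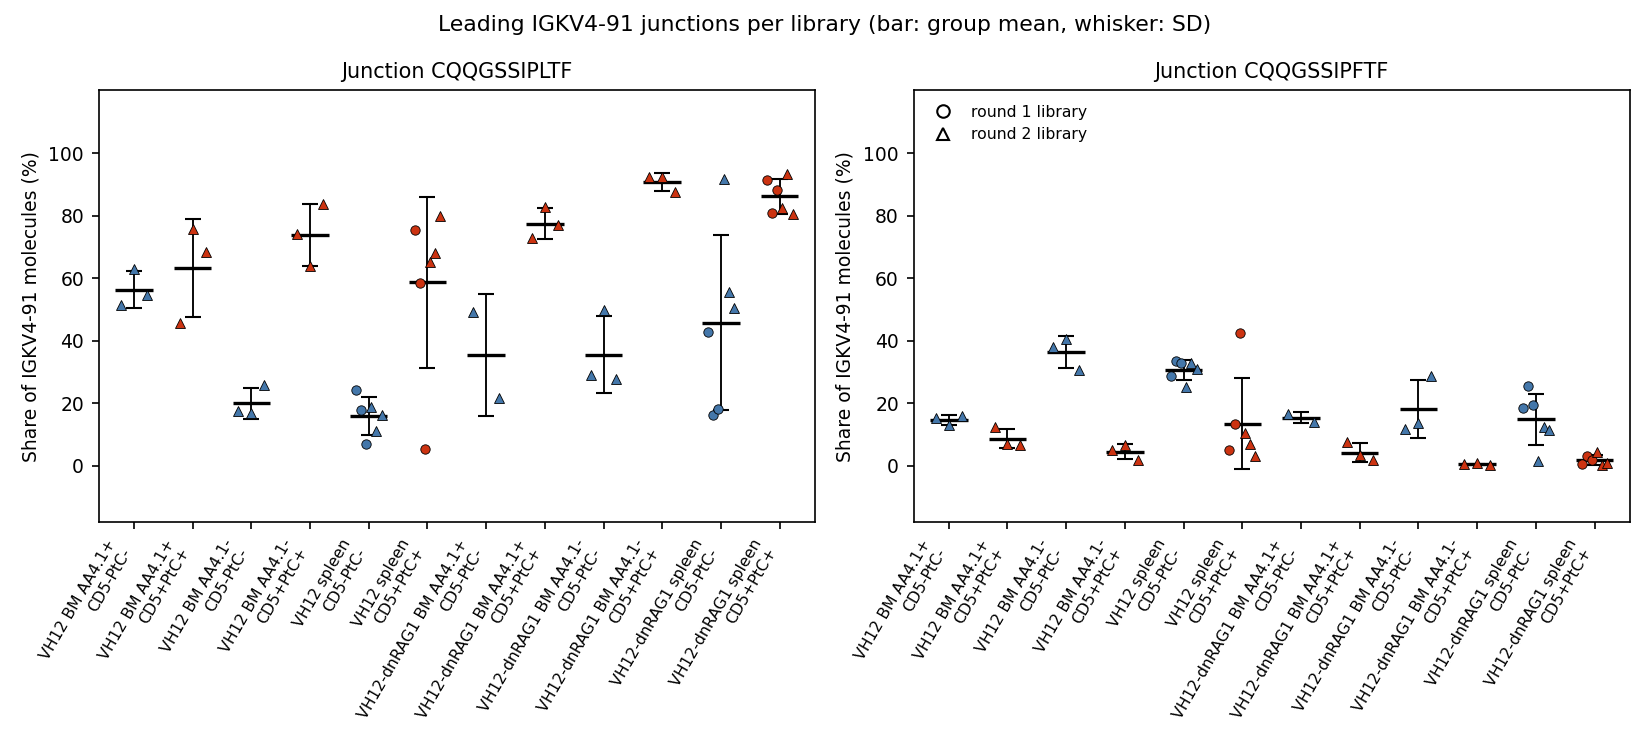
Share of IGKV4-91 molecules in percent (vertical axes) with junction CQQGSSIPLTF (left) or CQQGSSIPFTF (right) in each library of the VH12 and VH12-dnRAG1 populations; circles are round 1, triangles round 2, blue CD5-PtC- and red CD5+PtC+, with bars at the mean and whiskers of 1 SD. In spleen CD5+PtC+ cells the left junction averages 86.2% in VH12-dnRAG1 and 58.7% in VH12 mice, or 69.3% without VH12 replicate 3, which holds 5.32%.

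In bone marrow, immature AA4.1+ cells of the PtC gate were compared with those outside it. V mismatches made up 0.341% to 0.543% of bases read in the CD5+PtC+ and 0.159% to 0.218% in the CD5-PtC- libraries. The cause was not tested. IGKV4-91 rose in VH12 AA4.1+ CD5+PtC+ cells to 25.7% ± 6.72 from 1.56% ± 0.582 (n = 3 each; log2 4.04, SE 0.32, adjusted p = 8.11e-10) and in VH12-dnRAG1 to 25.6% ± 16.4 (n = 3) from 1.24% ± 0.848 (n = 2; log2 4.38, SE 0.71, adjusted p = 2.28e-07). With it rose the J-proximal genes IGKV3-7 (2.2% from 0.308% in VH12, 2.43% from 0.398% in VH12-dnRAG1) and IGKV3-5 (1.63% from 0.294%, 2.72% from 0.306%). IGKV4-86 fell to 1.90% from 16.2% in VH12 and to 1.38% from 13.8% in VH12-dnRAG1, IGKV1-122 to 0.703% from 3.28% and to 0.515% from 4.84%, and IGKV19-93 to 1.34% from 5.35% and to 0.898% from 4.90%. IGKV1-110 fell in VH12 to 6.12% from 10.03% (adjusted p = 0.0233) and was at 6.54% and 8.14% in VH12-dnRAG1 (0.667). IGKV14-126 did not pass in either genotype (adjusted p = 0.390 and 0.127).

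In VH12 AA4.1+ cells 6 of 7 IGKV3, 4 of 5 IGKV6 and 2 of 5 IGKV8 genes rose, and 11 of 27 IGKV4 and 3 of 5 IGKV1 genes fell, with 3 IGKV4 genes up. Of J-proximal genes 12 of 21 rose and 1 fell, of J-distal genes 8 of 19 fell and 0 rose, and of middle genes 3 of 27 rose and 10 fell. In VH12-dnRAG1 mice 6 of 7 IGKV3 and 7 of 23 J-proximal genes rose, and 7 of 27 IGKV4 genes, 6 of 20 J-distal genes and 7 of 27 middle genes fell, with 3 IGKV4 genes, 1 J-distal and 3 middle genes up. Among the 5 label genes 2 rose and 2 fell in VH12, and 2 rose and 1 fell in VH12-dnRAG1. In all, 15 of 67 genes rose and 19 fell in VH12, and 11 of 70 rose and 13 fell in VH12-dnRAG1, where leaving out 1 library gave 3 to 30 genes. With the mouse pool as a block 25 and 19 genes passed, which shared 24 of the 34 calls in VH12 and 14 of the 24 in VH12-dnRAG1. The effective number of genes was 27.6 ± 5.50 against 26.1 ± 2.56 in VH12 and 27.2 ± 11.7 against 31.0 ± 2.57 in VH12-dnRAG1 (exact permutation p = 0.8 each; smallest possible 0.1).

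In mature AA4.1- marrow cells the PtC gate held almost only IGKV4-91. It rose to 93.6% ± 1.76 from 13.8% ± 6.57 in VH12 (n = 3 each; log2 2.77, SE 0.65, adjusted p = 4e-05) and to 93.6% ± 1.36 from 4.72% ± 2.42 in VH12-dnRAG1 mice (log2 4.31, SE 0.74, adjusted p = 1.05e-05). IGKV3-7 was the other gene that rose in each genotype, to 2.92% from 0.186% in VH12 and to 2.74% from 0.440% in VH12-dnRAG1. IGKV5-43 fell to 0.0896% from 18.7% and to 0.0284% from 17.2%, IGKV1-110 to 0.155% from 8.41% and to 0.138% from 8.12%, and IGKV4-86 to 0.211% from 11.9% and to 0.210% from 10.4%. IGKV4-58 (log2 -7.32) and IGKV4-72 (-6.82) fell in VH12, and IGKV5-48 (-9.14) and IGKV1-122 (-8.04) in VH12-dnRAG1 cells. Of the label genes tested, 2 of 4 rose and 2 fell in each genotype.

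All 46 genes tested in VH12 AA4.1- marrow passed, 2 up and 44 down, and all 51 in VH12-dnRAG1, 2 up and 49 down. Thus 13 of 14 IGKV4 genes fell in VH12 and 14 of 15 in VH12-dnRAG1, 3 of 4 and 5 of 6 IGKV3 genes, and every tested member of the IGKV1, IGKV5, IGKV6, IGKV8, IGKV9, IGKV10, IGKV12, IGKV14, IGKV17 and IGKV19 families. IGKV4-91 took 93.6% of kappa molecules in the PtC gate of each genotype, so most other shares had to fall. These counts are therefore no evidence on single families. With TMM scaling (median shift 3.83 and 4.32) 15 were up and 15 down in VH12 and 12 up and 17 down in VH12-dnRAG1. With DESeq2 13 were up and 18 down, and 15 up and 15 down. IGKJ4 and IGKJ5 took 84.0% ± 5.57 against 74.2% ± 1.6 in VH12 and 91.6% ± 0.921 against 68.6% ± 4.85 in VH12-dnRAG1 cells (exact permutation p = 0.1 each, the smallest possible).

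Maturation outside the PtC gate was read from AA4.1- against AA4.1+ CD5-PtC- marrow cells of both genotypes. IGKV5-43 rose to 17.9% ± 3.34 (n = 6) from 2.40% ± 0.547 (n = 5; log2 2.90, SE 0.21, adjusted p = 2.06e-09), IGKV4-58 to 9.74% from 1.49% and IGKV4-91 to 9.24% ± 6.64 from 1.43% ± 0.616 (log2 2.62, adjusted p = 8.24e-06). IGKV1-135 fell to 3.90% ± 1.13 from 16.6% ± 1.83 (log2 -2.17), with IGKV17-121 (-1.36), IGKV4-55 (-1.16) and IGKV14-126 (-1.42). IGKV4-86 was at 11.1% and 15.2% (adjusted p = 0.0650, and 0.00512 with the mouse pool as a block), IGKV1-110 at 8.26% and 9.28% (0.488) and IGKV3-7 at 0.313% and 0.344% (0.325). With DESeq2 these 3 directions turned, to log2 changes of 0.36, 0.68 and 0.47, and IGKV1-110 passed (adjusted p = 0.0187). J-distal genes took 24.4% ± 4.31 of molecules against 48.8% ± 2.71, and J-proximal genes 29.9% ± 4.23 against 13.7% ± 2.82 (exact permutation p = 0.005 and adjusted p = 0.0333 each, in 5 of 5 pools). IGKJ4 and IGKJ5 took 71.4% ± 4.47 against 53.4% ± 3.83 (exact p = 0.01, adjusted p = 0.0667, in 5 of 5 pools).

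By gene, 16 of 19 J-distal genes fell and 0 rose, 3 of 20 J-proximal genes rose and 2 fell, and 5 of 24 middle genes rose and 14 fell. In the IGKV4 family 4 of 24 rose and 15 fell, 2 of 4 IGKV5 genes rose, 5 of 6 IGKV1, 3 of 3 IGKV9 and 3 of 3 IGKV14 genes fell, and 0 of 6 IGKV3 genes passed. In all, 8 of 63 genes rose and 32 fell; with DESeq2 18 were up and 14 down (median shift 0.79), and with all libraries of the round in 1 fit 5 were up and 16 down. Of the label genes 1 of 5 rose and 1 fell.

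In the PtC gate IGKV4-91 rose from immature to mature marrow cells, to 93.6% ± 1.40 from 25.7% ± 11.2 (n = 6 each; log2 1.87, SE 0.35, adjusted p = 6.74e-06), in 6 of 6 pools. IGKV1-110 fell to 0.147% from 6.33%, IGKV6-15 to 0.0229% from 2.08%, IGKV4-57-1 to 0.0207% from 2.27% and IGKV3-10 to 0.0108% from 1.16%. IGKV3-7 held 2.83% ± 1.33 and 2.32% ± 1.51 (adjusted p = 0.522). Of 52 genes 1 rose and 50 fell, among them 16 of 17 IGKV4 and 6 of 7 IGKV3 genes and 3 of 5 label genes, as shares of all kappa molecules. IGKV4-91 took most of these molecules in AA4.1- cells, so most other shares had to fall. With TMM scaling (median shift 4.67) 11 were up and 10 down, and IGKV4-86 and IGKV14-126, which fell by 2.96 and 2.88 on the log2 scale, turned to 1.53 and 1.70. IGKJ5 took 80.2% ± 10.6 against 41.8% ± 8.03 and IGKJ1 3.64% against 21.1% (exact permutation p = 0.005, adjusted p = 0.0333, in 6 of 6 pools each). IGKJ2 took 8.57% against 23.7% (exact p = 0.005, adjusted p = 0.1, lower in 6 of 6 pools).

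Spleen cells, which were not sorted by AA4.1, were compared with marrow AA4.1- cells of the same mice. The comparison therefore mixes tissue with the AA4.1 gate. In CD5+PtC+ cells IGKV4-91 held 94.4% ± 2.79 in spleen and 93.6% ± 1.40 in marrow (n = 6 each; adjusted p = 0.993), and IGKV3-7 2.11% and 2.83% (0.993). With edgeR 0 of 9 genes passed, 0 had an unadjusted p under 0.05, DESeq2 called 0, and none of the lists held a call. In CD5-PtC- cells IGKV3-7 rose in spleen to 1.93% ± 3.12 from 0.313% ± 0.172 (log2 2.51, adjusted p = 0.0160), and IGKV10-94 fell to 0.170% from 0.584% (log2 -1.70, adjusted p = 0.0456). IGKV10-94 lies outside the rule for named genes and was picked after its values were seen. IGKV4-91 held 18.3% ± 26.7 and 9.24% ± 6.64 (0.618), IGKV1-110 10.8% and 8.26% (0.861), IGKV4-86 9.29% and 11.1% (0.957), and IGKV14-126 0.0848% and 0.118% (0.705). These were 2 of 58 genes, with 10 at an unadjusted p under 0.05; 0 passed with the mouse pool as a block, and DESeq2 called 7 up and 6 down. Without VH12-dnRAG1 spleen replicate 4 there were 7 calls, IGKV3-7 was no longer among them (0.174) and IGKV1-110 was (0.0375). That library held 72.6% IGKV4-91, and without it the direction of IGKV4-91 turned, to a lower share in spleen. In the IGKV10 family 1 of 2 members fell, and 2 passed when adjusted over the list alone.

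The genotypes were also compared within each marrow population, without a V gene test. IGKV4-91 held 4.72% ± 2.42 in VH12-dnRAG1 and 13.8% ± 6.57 in VH12 AA4.1- CD5-PtC- cells (n = 3 each; exact permutation p = 0.1, the smallest possible), a difference of -9.03 that ranged from -11.7 to -5.35 with 1 library left out, the latter without VH12 replicate 3. In the other populations it held 1.24% and 1.56% (AA4.1+ CD5-PtC-, exact p = 0.6), 25.6% and 25.7% (AA4.1+ CD5+PtC+, exact p = 0.9), and 93.6% in both (AA4.1- CD5+PtC+, exact p = 1). In AA4.1- CD5+PtC+ cells the IGKJ4 and IGKJ5 share was 91.6% ± 0.921 in VH12-dnRAG1 and 84.0% ± 5.57 in VH12 mice (exact p = 0.1), and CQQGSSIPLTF made up 90.7% ± 2.84 and 73.8% ± 9.93 of their IGKV4-91 molecules (exact p = 0.1). The order was the opposite for the IGKJ4 and IGKJ5 share in AA4.1- CD5-PtC- cells (68.6% ± 4.85 and 74.2% ± 1.6, exact p = 0.2) and for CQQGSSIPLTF in AA4.1+ CD5-PtC- cells (35.4% ± 19.5 and 56.3% ± 5.87, exact p = 0.1).

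The overlap of kappa clonotypes was compared between cells of different gates and tissues. Different mice shared many of the same kappa joins. Neither the overlap nor its excess in the same mice can therefore show descent from common cells. Spleen CD5+PtC+ and CD5-PtC- libraries overlapped by 18.96% when they came from the same mice and by 16.04% when they came from different mice of the same genotype and round, a difference of 2.92 percentage points (12 and 24 pairs; exact permutation p = 0.0116, two-sided). Without VH12 replicate 3 the difference is 0.0396 (exact permutation p = 0.0509), and without VH12 replicate 1 or 2 it is 4.45 or 4.58 (exact p = 0.0509 each). Without both doubted spleen libraries it is -0.204 (exact p = 0.208). Where a pool is missing, here and below, the sets of mice hold unequal numbers of pairs. A difference without any excess in the same mice is then not 0, and p is taken around the mean of the regroupings. The size and sign of these differences therefore cannot be read alone. Spleen and marrow AA4.1- CD5+PtC+ libraries overlapped by 85.5% in the same and 78.5% in different mice, a difference of 7.0 (6 and 12 pairs; exact permutation p = 0.0556, with 0.0278 the smallest possible). It was 3.83 without VH12-dnRAG1 marrow replicate 2 or spleen replicate 5 (exact p = 0.25), and 2.75 by the Morisita-Horn index (exact p = 0.333). Further pairs were picked after the data had been seen. Spleen and marrow AA4.1- CD5-PtC- libraries overlapped by 61.5% in the same and 57.2% in different mice, a difference of 4.23 (exact permutation p = 0.0278, the smallest possible; 2.90 without the doubted library, exact p = 0.0833). Marrow AA4.1+ and AA4.1- libraries overlapped by 26.9% and 26.4% in the CD5+PtC+ gate (exact p = 0.139) and by 45.8% and 43.1% in the CD5-PtC- gate (exact p = 0.0833, the smallest possible). No library was a copy of another: among 1540 pairs 0 had identical counts, and the highest overlap was 92.8%.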

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

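The tests of swapped labels, of misread V calls and of both expansions of CD5-PtC- cells were chosen after the results had been seen, and the other explanations weighed here had their predictions written first. The measures of the VH12 and VH12-dnRAG1 spleen groups gave 56 sets of 6 values. Among these, 15 values lay further from the rest than Dixon's 95% limit. All came from VH12 CD5+PtC+ replicates 2 and 3 and VH12-dnRAG1 CD5-PtC- replicate 4. Measures of 1 library go together, so the chance rate of about 1 in 20 for separate sets is no yardstick for this count.

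VH12-dnRAG1 spleen CD5-PtC- replicate 4 stood apart from the other 5 libraries of its group. Its IGKV4-91 share was 72.6%, its IGKV3-7 share 8.25%, its effective number of IGKV genes 4.11, its effective number of clonotypes 14.99 and its largest clonotype 42.7% of molecules. A swap of labels within the mouse pool was excluded, since the CD5+PtC+ library of the same mice held 89.7% IGKV4-91. An expansion of IGKV4-91 cells alone was excluded, since clonotypes outside IGKV4-91 overlapped by at most 22.5% with the other CD5-PtC- libraries, which overlapped by 63.7% to 72.1% with each other (Morisita-Horn index 7.03% to 10.7% against 85.1% to 94.6%). An expansion of CD5-PtC- cells that took in other genes as well stays open: IGKJ5 took 91.9% of the IGKV4-91 molecules against at most 64.3% in the other 5 libraries, but growth of a clone with an IGKJ5 join would raise that share as well. Material of CD5+PtC+ cells of the same mice may account for the share: the IGKV4-91 clonotypes overlapped by 86.1% with that library and by at most 78.2% with those of other pools of the round, but by up to 84.8% with pools of round 1, which are other mice. This explanation stays open too. Its other prediction, that the rest keeps the shares of a CD5-PtC- library, was not met. Outside IGKV4-91 the library's V gene shares overlapped by 39.3% with the mean of CD5-PtC- and by 70.5% with that of CD5+PtC+ libraries. That likeness is not in itself against CD5+PtC+ material. The lambda share of 12.9% lay within the 6.83% to 13.9% of the other CD5-PtC- libraries and above the 0.272% to 5.66% of CD5+PtC+ libraries. The library's clonotypes outside IGKV4-91 overlapped by 20.8% to 47.4% with CD5+PtC+ libraries, with 47.4% for the same mice, but by the Morisita-Horn index (33.0% to 87.3%) the same mice came 5th of 6 with 80.3%. No other biological explanation was tested.

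VH12 spleen CD5+PtC+ replicate 3 looked unlike the other PtC-binding libraries. Its IGKV4-91 share was 3.24%, IGKV4-86 12.6%, IGKV1-110 13.9% and lambda 19.5%, with an effective number of 25.9 IGKV genes and 144 clonotypes. Within IGKV4-91, IGKJ5 took 15.5%, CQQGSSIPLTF 5.32% and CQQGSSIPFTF 42.6%. A swap of labels was excluded, since the CD5-PtC- library of the same mice held 2.45% IGKV4-91. Misread V calls were excluded, since 94.3% of the molecules outside IGKV4-91 lay in clonotypes of that CD5-PtC- library. The test of low base quality was void, with IGKV4-91 in 0% of 2 clean sequences (Wilson upper limit 65.8%). CD5-PtC- material of the same mice in place of CD5+PtC+ cells is a candidate explanation: clonotypes outside IGKV4-91 overlapped by 83.4% with the library of the same mice and by at most 58.0% with other pools of the round. No biological explanation was tested.

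The IGKV4-91 share in the PtC gate was lower in AA4.1+ than in AA4.1- marrow. Cells of the AA4.1+ CD5-PtC- kind in the gate were excluded as the whole cause, since with IGKV4-91 left out of the counts 35 genes in VH12 and 26 in VH12-dnRAG1 mice still differed between the gates (edgeR, adjusted p under 0.05). The smaller libraries of AA4.1+ cells stay open: the difference was 67.4 percentage points after all libraries had been drawn down to the same depth, but random drawing leaves a share where it was, so the test was void. A gain of IGKV4-91 cells during maturation could give the same values, and it was not tested.

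VH12 spleen CD5+PtC+ replicate 2 had an IGKV3-7 share of 9.64%, the highest of its group. The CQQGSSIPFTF share of IGKV4-91 in CD5+PtC+ minus CD5-PtC- cells was -14.9 ± 11.2 percentage points in spleen and -24.8 ± 9.99 in marrow AA4.1- cells. The difference between the tissues was 9.90 over 6 pools (exact sign-flip p = 0.0312, the smallest possible, in 1 of 21 differences tested). Without the pool of VH12-dnRAG1 spleen CD5-PtC- replicate 4, a choice made after the data had been seen, it was 9.08 over 5 pools (exact sign-flip p = 0.0625, the smallest possible).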

How the results depend on the processing

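Leaving out the doubted libraries was chosen after the data had been seen, as were the further pairs of populations for clonotype sharing; the other alternatives were fixed beforehand. Of 43 results that answer a comparison, the alternatives kept the direction and the side of the threshold in 209 instances, lost the threshold in 16, turned the direction in 19 and moved a count by over 1.5 times in 54. Of 117 results for named genes they kept both in 797 instances, lost the threshold in 100, crossed it in 50 and turned the direction in 58. Fits that leave out 1 library in turn are not in these counts. TMM and DESeq2 set the median gene to no change, so where IGKV4-91 fills most of a library they lift every other gene. The shift is by construction. Where not given above, its median with TMM was 1.16 for CD5+PtC- cells of dnRAG1 spleen, 1.33 and 0.32 for the genotypes in spleen CD5+PtC+ and CD5-PtC- cells, and 0.12 for VH12-dnRAG1 AA4.1+ marrow. For spleen against marrow it was 0.23 in CD5-PtC- and 0.21 in CD5+PtC+ cells. Rounds alone hold 3 libraries against 3 and cannot reach an exact p of 0.05. For all other changes below the cause was not tested. The block of mouse pools changed the call of no named gene beyond those in the text above. Keeping sequences that are not productive was not run, because the files hold none. The smallest library, dnRAG1 CD5-PtC- replicate 1, held 2566 molecules, and the AA4.1+ CD5+PtC+ marrow libraries held 3409 to 6225. Values in brackets are those of the text above, and a library left alone in its group was assumed to vary like the other group.

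With TMM factors, genes past the threshold numbered 3 (10) for the PtC gates of dnRAG1 spleen, 14 (2) for the PtC gates of VH12 spleen, 22 (44) for the PtC gates of VH12-dnRAG1 spleen and 30 (46) for the PtC gates of VH12 AA4.1- marrow. The count was 29 (51) for the PtC gates of VH12-dnRAG1 AA4.1- marrow, 21 (51) for AA4.1- against AA4.1+ CD5+PtC+ marrow and 5 (2) for spleen against marrow CD5-PtC- cells. Turned log2 changes were 0.66 for IGKV4-86 (the PtC gates of dnRAG1 spleen), 0.71 for IGKV4-86 (CD5+PtC- cells of dnRAG1 spleen) and 0.18 for IGKV3-7 (VH12 against WT). Log2 changes turned to -0.38 for IGKV3-7 (the genotypes in spleen CD5+PtC+ cells), 0.083 for IGKV1-110 and 0.056 for IGKV14-126 (the genotypes in spleen CD5-PtC- cells) and 0.70 for IGKV1-110, 0.48 for IGKV3-7 and 0.40 for IGKV4-86 (AA4.1- against AA4.1+ CD5-PtC- marrow). Directions turned, with log2 changes of 1.70 for IGKV14-126 and 1.53 for IGKV4-86 (AA4.1- against AA4.1+ CD5+PtC+ marrow) and 0.077 for IGKV1-110 (spleen against marrow CD5+PtC+ cells). With DESeq2, genes past the threshold numbered 4 (0) for CD5+PtC- cells of dnRAG1 spleen, 14 (2) for the PtC gates of VH12 spleen and 29 (44) for the PtC gates of VH12-dnRAG1 spleen. The count was 30 (51) for the PtC gates of VH12-dnRAG1 AA4.1- marrow, 22 (51) for AA4.1- against AA4.1+ CD5+PtC+ marrow and 13 (2) for spleen against marrow CD5-PtC- cells. Turned log2 changes were 0.77 for IGKV4-86 (the PtC gates of dnRAG1 spleen), 0.51 for IGKV4-86 (CD5+PtC- cells of dnRAG1 spleen) and 0.0054 for IGKV3-7 (VH12 against WT). Log2 changes turned to -0.21 for IGKV3-7 (the genotypes in spleen CD5+PtC+ cells), 0.092 for IGKV1-110 and 0.074 for IGKV14-126 (the genotypes in spleen CD5-PtC- cells) and 0.68 for IGKV1-110, 0.47 for IGKV3-7 and 0.36 for IGKV4-86 (AA4.1- against AA4.1+ CD5-PtC- marrow). Directions turned, with log2 changes of 1.70 for IGKV14-126 and 1.53 for IGKV4-86 (AA4.1- against AA4.1+ CD5+PtC+ marrow).

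Without the filter on low shares, genes past the threshold numbered 25 (10) for the PtC gates of dnRAG1 spleen, 4 (0) for CD5+PtC- cells of dnRAG1 spleen, 1 (0) for dnRAG1 against WT and 23 (10) for VH12 against WT. The count was 23 (2) for the PtC gates of VH12 spleen, 75 (46) for the PtC gates of VH12 AA4.1- marrow and 82 (51) for AA4.1- against AA4.1+ CD5+PtC+ marrow. With all libraries of the rounds in 1 fit, genes past the threshold numbered 2 (10) for the PtC gates of dnRAG1 spleen, 0 (10) for VH12 against WT and 48 (2) for the PtC gates of VH12 spleen. The count was 12 (0) for the genotypes in spleen CD5+PtC+ cells, 0 (1) for the genotypes in spleen CD5-PtC- cells and 14 (34) for the PtC gates of VH12 AA4.1+ marrow. The count was 10 (24) for the PtC gates of VH12-dnRAG1 AA4.1+ marrow, 21 (40) for AA4.1- against AA4.1+ CD5-PtC- marrow and 1 (2) for spleen against marrow CD5-PtC- cells. With the mouse pool as a block, genes past the threshold numbered 50 (2) for the PtC gates of VH12 spleen and 0 (2) for spleen against marrow CD5-PtC- cells. For the effective number of IGKV genes the difference was -17.2 (-17.2, exact p = 0.0625) for the PtC gates of VH12 spleen. Without ambiguous V calls, genes past the threshold numbered 1 (0) for CD5+PtC- cells of dnRAG1 spleen. The IGKV4-91 share differed by -0.000442 (0.00332, exact p = 1) for the genotypes in marrow AA4.1- CD5+PtC+ cells.

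Counting each unique sequence once, genes past the threshold numbered 2 (10) for the PtC gates of dnRAG1 spleen, 1 (0) for CD5+PtC- cells of dnRAG1 spleen and 17 (10) for VH12 against WT. The count was 44 (2) for the PtC gates of VH12 spleen, 0 (1) for the genotypes in spleen CD5-PtC- cells and 0 (2) for spleen against marrow CD5-PtC- cells. The IGKV4-91 share differed by -4.06 (0.00332, exact p = 0.2) for the genotypes in marrow AA4.1- CD5+PtC+ cells. For the IGKJ4 and IGKJ5 share the difference was -1.59 (0.283, exact p = 0.7) for the genotypes in marrow AA4.1+ CD5+PtC+ cells. Log2 changes turned to 0.24 for IGKV14-126 and -0.049 for IGKV4-86 (dnRAG1 against WT), 0.43 for IGKV14-126 (the genotypes in spleen CD5-PtC- cells) and 0.0016 for IGKV1-110 and 0.0050 for IGKV3-7 (AA4.1- against AA4.1+ CD5-PtC- marrow). Counting each clonotype once, genes past the threshold numbered 5 (10) for the PtC gates of dnRAG1 spleen, 4 (0) for CD5+PtC- cells of dnRAG1 spleen, 28 (10) for VH12 against WT and 24 (2) for the PtC gates of VH12 spleen. The count was 0 (1) for the genotypes in spleen CD5-PtC- cells, 29 (46) for the PtC gates of VH12 AA4.1- marrow, 23 (51) for the PtC gates of VH12-dnRAG1 AA4.1- marrow and 0 (2) for spleen against marrow CD5-PtC- cells. The IGKV4-91 share differed by -2.76 (13.6, exact p = 0.79) for the genotypes in spleen CD5+PtC+ cells and -6.20 (0.00332, exact p = 0.2) for the genotypes in marrow AA4.1- CD5+PtC+ cells. For the IGKJ4 and IGKJ5 share the difference was 1.41 (14.2, exact p = 0.335) for the PtC gates of VH12 spleen and 4.67 (18.5, exact p = 0.09) for the PtC gates of VH12-dnRAG1 spleen. The IGKJ4 and IGKJ5 share differed by -1.59 (6.08, exact p = 0.37) for the genotypes in spleen CD5-PtC- cells and -0.0851 (0.283, exact p = 0.9) for the genotypes in marrow AA4.1+ CD5+PtC+ cells. For the effective number of IGKV genes the difference was 0.538 (-3.90, exact p = 0.96) for the genotypes in spleen CD5+PtC+ cells and 1.88 (-5.24, exact p = 0.565) for the genotypes in spleen CD5-PtC- cells. The rise of IGKV4-91 between the gates, VH12-dnRAG1 minus VH12, was -2.84 (5.33, exact p = 0.8). Directions turned, with log2 changes of 0.052 for IGKV4-86 (CD5+PtC- cells of dnRAG1 spleen), 0.15 for IGKV14-126 (dnRAG1 against WT) and -0.11 for IGKV3-7 and -0.11 for IGKV4-91 (the genotypes in spleen CD5+PtC+ cells). Among named genes, values turned to 0.29 for IGKV14-126 and -0.10 for IGKV4-91 (the genotypes in spleen CD5-PtC- cells), 0.15 for IGKV1-110 and -0.029 for IGKV14-126 (the PtC gates of VH12 AA4.1+ marrow) and 0.24 for IGKV1-110 (the PtC gates of VH12-dnRAG1 AA4.1+ marrow). The log2 change became 0.22 for IGKV1-110 and 0.12 for IGKV3-7 (AA4.1- against AA4.1+ CD5-PtC- marrow), 0.056 for IGKV4-86 (AA4.1- against AA4.1+ CD5+PtC+ marrow) and 0.00084 for IGKV4-86 (spleen against marrow CD5-PtC- cells).

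After drawing down to a fixed depth, the IGKJ4 and IGKJ5 share differed by -0.100 (0.283, exact p = 1) for the genotypes in marrow AA4.1+ CD5+PtC+ cells. With the Morisita-Horn index, the clonotype overlap of spleen gates, same minus different mice, was 2.52 (2.92, exact p = 0.0772). In round 1 alone, genes past the threshold numbered 0 (2) for the PtC gates of VH12 spleen and 0 (1) for the genotypes in spleen CD5-PtC- cells. For the IGKV4-91 share the difference was 58.8 (72.1, exact p = 0.2) for the PtC gates of VH12 spleen, 88.3 (77.5, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen and -1.65 (8.25, exact p = 0.2) for the genotypes in spleen CD5-PtC- cells. The IGKJ4 and IGKJ5 share differed by 12.5 (14.2, exact p = 0.2) for the PtC gates of VH12 spleen and 21.3 (18.5, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen. For the effective number of IGKV genes the difference was -13.9 (-17.2, exact p = 0.3) for the PtC gates of VH12 spleen and -17.6 (-15.8, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen. Among named genes, values turned to 0.20 for IGKV1-110 and -0.83 for IGKV4-91 (the genotypes in spleen CD5-PtC- cells). In round 2 alone, genes past the threshold numbered 49 (2) for the PtC gates of VH12 spleen and 0 (1) for the genotypes in spleen CD5-PtC- cells. The IGKV4-91 share differed by 85.4 (72.1, exact p = 0.1) for the PtC gates of VH12 spleen, 66.7 (77.5, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen and -0.606 (13.6, exact p = 0.8) for the genotypes in spleen CD5+PtC+ cells. For the IGKJ4 and IGKJ5 share the difference was 15.9 (14.2, exact p = 0.1) for the PtC gates of VH12 spleen and 15.6 (18.5, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen. The effective number of IGKV genes differed by -20.5 (-17.2, exact p = 0.1) for the PtC gates of VH12 spleen, -14.1 (-15.8, exact p = 0.1) for the PtC gates of VH12-dnRAG1 spleen and 0.0444 (-3.90, exact p = 0.9) for the genotypes in spleen CD5+PtC+ cells. The rise of IGKV4-91 between the gates, VH12-dnRAG1 minus VH12, was -18.8 (5.33, exact p = 1). The log2 change became -0.46 for IGKV3-7 (the PtC gates of VH12-dnRAG1 spleen) and 0.95 for IGKV1-110, 0.50 for IGKV4-86 and -0.0093 for IGKV4-91 (the genotypes in spleen CD5+PtC+ cells).

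Without the doubted libraries, genes past the threshold numbered 1 (10) for the PtC gates of dnRAG1 spleen, 52 (2) for the PtC gates of VH12 spleen, 4 (1) for the genotypes in spleen CD5-PtC- cells and 7 (2) for spleen against marrow CD5-PtC- cells. The IGKV4-91 share differed by -1.49 (13.6, exact p = 0.665) for the genotypes in spleen CD5+PtC+ cells and -3.31 (8.25, exact p = 0.01) for the genotypes in spleen CD5-PtC- cells. For the effective number of IGKV genes the difference was 0.175 (-3.90, exact p = 0.46) for the genotypes in spleen CD5+PtC+ cells. The clonotype overlap of spleen gates, same minus different mice, was -0.204 (2.92, exact p = 0.208). With pools missing, a difference without any excess in the same mice is not 0, so this sign cannot be read alone. Among named genes, values turned to 0.54 for IGKV4-86 (CD5+PtC- cells of dnRAG1 spleen), 0.042 for IGKV14-126 and -0.81 for IGKV4-86 (dnRAG1 against WT) and 0.78 for IGKV1-110, -0.20 for IGKV3-7, 0.48 for IGKV4-86 and -0.018 for IGKV4-91 (the genotypes in spleen CD5+PtC+ cells). The log2 change became 0.16 for IGKV1-110, -0.42 for IGKV3-7 and -0.88 for IGKV4-91 (the genotypes in spleen CD5-PtC- cells) and -0.31 for IGKV4-91 (spleen against marrow CD5-PtC- cells).

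With each library left out in turn, the genes past the threshold numbered 0 to 27 for the PtC gates of dnRAG1 spleen, 0 to 45 for CD5+PtC- cells of dnRAG1 spleen, 3 to 28 for VH12 against WT and 0 to 52 for the PtC gates of VH12 spleen. They numbered 0 to 4 for the genotypes in spleen CD5-PtC- cells, 3 to 30 for the PtC gates of VH12-dnRAG1 AA4.1+ marrow and 0 to 7 for spleen against marrow CD5-PtC- cells. The left-out range of the difference in the IGKV4-91 share was -1.49 to 17.5 for the genotypes in spleen CD5+PtC+ cells, -3.31 to 10.9 for the genotypes in spleen CD5-PtC- cells and -0.916 to 0.284 for the genotypes in marrow AA4.1+ CD5-PtC- cells. It was -7.24 to 8.90 for the genotypes in marrow AA4.1+ CD5+PtC+ cells and -0.972 to 0.730 for the genotypes in marrow AA4.1- CD5+PtC+ cells. The left-out range of the difference in the IGKJ4 and IGKJ5 share was 6.05 to 12.4 for the genotypes in spleen CD5+PtC+ cells, 4.24 to 7.77 for the genotypes in spleen CD5-PtC- cells and -4.08 to 4.12 for the genotypes in marrow AA4.1+ CD5+PtC+ cells. The left-out range of the difference in the effective number of IGKV genes was -4.78 to 0.175 for the genotypes in spleen CD5+PtC+ cells and -6.23 to -2.57 for the genotypes in spleen CD5-PtC- cells. The difference between genotypes in the rise of IGKV4-91 ranged from -8.93 to 17.4. The same-minus-different clonotype overlap of spleen gates ranged from 0.0396 to 5.20, sizes that cannot be read against 0 once a pool is missing. Log2 changes that crossed 0 with a library left out ranged from -0.42 to 0.46 for IGKV1-110 and -2.12 to 0.54 for IGKV4-86 (CD5+PtC- cells of dnRAG1 spleen) and -0.50 to 0.15 for IGKV14-126, -0.81 to 0.97 for IGKV4-86 and -0.31 to 0.0027 for IGKV4-91 (dnRAG1 against WT). Others ranged from -3.50 to 0.78 for IGKV1-110, -0.63 to 1.13 for IGKV3-7, -2.50 to 0.48 for IGKV4-86 and -0.018 to 0.43 for IGKV4-91 (the genotypes in spleen CD5+PtC+ cells) and -0.31 to 0.16 for IGKV1-110, -0.42 to 1.29 for IGKV3-7 and -0.88 to 0.68 for IGKV4-91 (the genotypes in spleen CD5-PtC- cells). Others ranged from -0.31 to 1.31 for IGKV4-91 (spleen against marrow CD5-PtC- cells) and -0.54 to 0.60 for IGKV1-110 and -0.0013 to 0.027 for IGKV4-91 (spleen against marrow CD5+PtC+ cells).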

Other observations

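The lambda share of light chain molecules was 2.42% ± 1.97 in CD5+PtC+ and 10.3% ± 2.70 in CD5-PtC- cells of VH12-dnRAG1 spleen, and 0.952% ± 0.770 in AA4.1- against 18.4% ± 4.73 in AA4.1+ CD5+PtC+ marrow (exact permutation p = 0.005, adjusted p = 0.05, lower in 6 of 6 pools each). In dnRAG1 spleen it was 32.4% ± 9.95 in CD5+PtC+ and 19.9% ± 6.73 in CD5-PtC- cells (exact permutation p = 0.3). IGLV2 made up 32.0% ± 5.93 of lambda molecules in AA4.1- and 17.9% ± 3.55 in AA4.1+ CD5-PtC- marrow cells, and 12.4% ± 3.64 in VH12-dnRAG1 against 26.0% ± 6.15 in VH12 spleen CD5+PtC+ cells (exact permutation p = 0.005, adjusted p = 0.05 each). The mean number of N/P nucleotides at the kappa join was 0.0885 ± 0.0773 in CD5+PtC+ and 0.252 ± 0.0414 in CD5-PtC- cells of VH12 spleen. In CD5-PtC- cells it was 0.154 in VH12-dnRAG1 against 0.252 in VH12 mice (exact permutation p = 0.005, adjusted p = 0.025 each).

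The use of IGKJ4 and IGKJ5 outside IGKV4-91 lay below the range of the CD5-PtC- libraries of the genotype in 11 of 11 spleen CD5+PtC+ libraries, with the doubted ones left out. This was set against sequences carried over from CD5-PtC- cells after the result had been seen, but carry-over would raise the share, so the test was void and the cause is open. The higher IGKJ5 share within IGKV4-91 in VH12-dnRAG1 than in VH12 spleen CD5+PtC+ cells might reflect 1 amplified clonotype. Without VH12 replicate 3, the difference was 14.8 percentage points with each clonotype counted once, against 15.1 by molecules. Misread copies of 1 join would count as further clonotypes, so the test could not exclude this. The junction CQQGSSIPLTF had 49 nucleotide versions in VH12-dnRAG1 and 46 in VH12 libraries of that gate. With all libraries the shares by molecules were 87.3% and 62.6%. The prediction was written first, but leaving out replicate 3 was chosen after the data had been seen.

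Other splits of the same libraries were tried against the real grouping, with predictions written first. Each set of 100 splits was drawn from 200 possible. For the PtC gates of VH12 spleen the real split was the only 1 of 100 as large (real count 2, highest other 1). The margin is small, and the count was 0 in round 1 alone and without some single libraries, so chance stays open there. For the PtC gates of VH12-dnRAG1 spleen chance was excluded (44 and 0, 1 of 100). It was also excluded for AA4.1- against AA4.1+ CD5+PtC+ marrow (51 and 1, 1 of 100). For the genotypes in spleen CD5-PtC- cells the share of splits was under 0.05 (real count 1, highest other 1, 3 of 100 as large). Other splits reached the same count of 1, and each round alone gave 0 genes, so chance stays open there. In CD5-PtC- marrow 2 of 100 splits were as large as the real 40, and the other of these called 46, for a reason that was not tested; among 15 splits that part the pairs the highest was 30. For spleen against marrow CD5-PtC- cells 2 of 100 splits were as large as the real 2, with 2 the highest other, and 1 the highest of 21 that part the pairs. A real count of 0 makes every split as large, so the test says nothing on chance for the genotypes in spleen CD5+PtC+ cells (real count 0, highest other 7, 100 of 100 as large) or for spleen against marrow CD5+PtC+ cells (0 and 3, 100 of 100). With 10 splits there are too few for a share under 0.05: the real and highest other counts were 34 and 0 in VH12 AA4.1+, 46 and 0 in VH12 AA4.1-, and 51 and 0 in VH12-dnRAG1 AA4.1- marrow, each with 1 of 10 as large.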
